A study of Mus musculus with 6 samples.

How the data were processed

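RNA from cultured EO771-tdT-Parental and EO771-tdT-LM2 cells, 3 libraries of each, was sequenced after library preparation with an mRNA kit, per the labels. Groups and replicate numbers were taken from the sample titles. The meaning of the tag Ac6 in the Parental titles was not given in the sources used here and was not used.

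The authors deposited 1 table per library with estimated counts, TPM, length and effective length of 117486 transcripts. These were made with kallisto 0.46.2 against build GRCm39, per the submitters' processing notes, which also list FastQC, MultiQC and edgeR 3.32.1. The transcript set and the treatment of strand are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The deposited TPM values, scaled by kallisto for effective length and depth per the labels, served only to weight the effective lengths of transcripts in an alternative setting. The deposited lengths, in bases, were otherwise not used. The authors also deposited 11005 log2 fold changes between the lines, computed per gene symbol and rounded to 2 decimals before deposit, with edgeR listed in the submitters' processing notes and its filter and model not given. The log base and direction are not written in that table. They were read from its closeness to the LM2 minus Parental log2 values computed here.

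Transcripts were assigned to genes by their Ensembl identifiers with GENCODE release M21, which is on GRCm38. As the builds differ, the annotation gave names, gene types, chromosomes and the order of neighbours, and no coordinate is reported. Of all transcripts 116408 (99.1%) matched 1 of 35905 genes. The other 1078 held 0.426% to 0.448% of the counts of a library and were left out of library sizes and tests. The gene symbols Aldoa and Ddit3 each matched 2 gene identifiers. Estimated counts were summed per gene and rounded to whole numbers. kallisto splits reads between transcripts that share sequence, so genes with close copies are uncertain. For named genes the share of their 31-base words that occur in transcripts of other genes was computed from the reference transcripts.

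Depth ranged from 33922699 to 45849019 estimated counts per library. The 20 most abundant genes took 6.80% to 6.94% of the counts, and mitochondrial genes 1.06% to 1.43%.

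The comparison, the gene lists, the rule for named genes and the alternatives were written down before the data were examined. The comparison was fitted with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr, scaled with TMM factors and tested with the robust quasi-likelihood fit, LM2 minus Parental, with no covariate. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. Levels are CPM after TMM scaling, given as mean and SD over 3 libraries. The standard error of a log2 fold change was approximated from the fold change and its F statistic. Of all tested genes, 8654 had an unadjusted p below 0.05.

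The 38 gene lists came from textbook knowledge. They covered epithelial, basal, luminal and mesenchymal genes, collagens and matrix, proteases, integrins, lung metastasis genes of earlier work, pathway targets (TGF-beta, Wnt, Notch, YAP and TAZ, interferon, NF-kB, p53, MAP kinase feedback), antigen presentation, chemokines, receptor tyrosine kinases, the cell cycle, metabolism, stress, ribosomal and mitochondrial genes, stemness, and markers of leukocytes, endothelium, lung epithelium, fibroblasts and adipocytes and sex-linked genes. Each list with at least 5 tested members was tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation. Adjustment was over the 35 lists.

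The rule for named genes took the 12 largest rises and the 12 largest falls among called genes with at least 10 CPM in the higher line and no overlap of libraries. It added the 6 most abundant called genes with an absolute log2 fold change over 1. From each list it took up to 4 called members of at least 5 CPM by size of change, on both sides where both existed, and up to 2 abundant members that did not pass. For markers of other cell types it took the most abundant member. Predicted and unnamed genes were passed over. A few genes that the rule gave, or that belong to the lists, are not reported here. The rule gave 220 genes, of which 153 passed the threshold.

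The tests were also run on simulated counts for LM2 against Parental over 13247 genes. These had the means and library sizes of these data and the spread of the dispersion trend, not of each gene. For the gene tests only 200 genes were changed, against 8272 called in the data. Recovery and false calls were therefore not tested with so many changes. Of 50 genes changed at each size, edgeR recovered 62% at 1.2-fold, 76% at 1.5-fold, 88% at 2-fold and 96% at 4-fold, and 5.29% of its 170 calls were false. DESeq2 1.42.0 recovered 56%, 72%, 84% and 90%, and 6.21% of its 161 calls were false. With limma voom 6.4% of 172 calls were false. Camera called the 1 list that had been moved and 0 of 37 others. The simulated genes varied independently, so these counts do not show how often camera calls lists whose members vary together.

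The alternatives were DESeq2, limma voom, median-of-ratios scaling, library totals, no low-count filter, at least 1 CPM in 3 libraries, an offset for effective length, protein-coding genes alone, leaving out the 20 most abundant genes, non-robust dispersions, transcripts as features, a test against a log2 fold change of 1, fry, a replicate block and leaving out each library. Centring on chromosome medians was added after the data were seen. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.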

Results

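Gene expression was measured by RNA sequencing in 2 related lines of mouse breast cancer cells, which the labels name EO771-tdT-Parental and EO771-tdT-LM2 and which are called Parental and LM2 here. EO771 is a mouse mammary tumour line that grows in culture. The labels do not spell out how LM2 was derived from the parental cells. Each line was sampled in 3 libraries, grown for 48 h to about 75% confluence in medium with 10% serum. The libraries held 45849019, 36597892 and 40476805 estimated counts for Parental replicates 1 to 3, and 34711938, 33922699 and 38182191 for LM2 replicates 1 to 3. The labels do not say whether the replicates came from separate cultures, so the p-values measure only the spread between these samples, which may be technical.

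The series was designed to compare the transcriptomes of the lines, and that single comparison is described here. Among genes of at least 10 CPM in the higher line, podoplanin, type XII collagen and smooth muscle actin genes were among the largest rises in LM2, and the transcription cofactor gene Ldb2 and the transcription factor gene Gli1 among the largest falls. Most tested genes of the extracellular matrix, interferon response and antigen presentation lists were higher in LM2, and most of the mitotic, ribosomal protein and oxidative phosphorylation lists were lower, by small amounts. None of the 19 list calls held when the correlation between genes was estimated from the data. Genes on chromosome 4 were higher and genes on chromosomes 8 and 10 lower along the whole chromosome. In all, 8272 of 13247 tested genes differed between the lines by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 4156 higher and 4116 lower in LM2. An absolute log2 fold change over 1 was reached by 1140 of them, 862 higher and 278 lower, and by 754 (586 higher and 168 lower) with a filter of at least 1 CPM in 3 libraries.

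The libraries of each line were close to one another. Pearson correlations of log2 CPM across genes, which are not independent replicates, were 0.991 to 0.994 within a line and 0.962 to 0.964 between lines. The first principal component held 77.2% of the variance and separated the lines, and the second held 6.92%. The biological coefficient of variation was 0.0373. In 8879 tested genes (67.0%) the 3 LM2 libraries did not overlap the 3 Parental libraries, against 10% by chance. Pairs of libraries of one line differed by more than counting noise, with a chi-square per degree of freedom of 3.06 to 7.56, which does not tell separate cultures from technical replicates.

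Among genes of at least 10 CPM in the higher line and with no overlap between the lines, the largest rises were in genes close to undetected in Parental cells. Col12a1, which encodes a collagen that associates with collagen I fibrils, went from 0.0468 ± 0.0357 CPM in Parental to 68.8 ± 8.34 CPM in LM2 (SD, n = 3 each), a log2 fold change of 10.36 ± 0.23 (SE). Its counts summed to 6 over the Parental libraries and to 7309 over the LM2 libraries. Pdpn, encoding podoplanin, a membrane glycoprotein of fibroblasts, lymphatic endothelium and some carcinomas, rose from 0.0532 ± 0.055 to 61.7 ± 1.58 CPM, a log2 fold change of 9.99 ± 0.14. The endocytosis factor Fcho1 rose by 8.62 on the log2 scale, the secreted phospholipase Pla2g5 by 8.31, the galectin Lgals7 by 8.04 and the sorting nexin Snx18 by 7.92. Il2rg, the common gamma chain of interleukin receptors, rose by 7.54, and 28.7% of its 31-base words occur in other genes, so its level is less certain. Actg2, the smooth muscle gamma actin, rose by 7.44 from 0.252 to 44.7 CPM. The synuclein Sncg rose by 7.19, the guidance ligand Slit1 by 7.16, the scavenger receptor Scarf1 by 7.12 and the dipeptidase Dpep1 by 6.95. Fitted folds of this size depend on a few Parental counts, between 6 and 40 per gene over 3 libraries.

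Among genes chosen in the same way, falls were smaller in size, with one exception. Ldb2, which encodes a cofactor of LIM domain transcription factors, was 184-fold lower in LM2, at 0.0545 ± 0.0436 CPM (SD, n = 3), a log2 fold change of -7.52 ± 0.22. Its counts summed to 1341 over the Parental libraries and to 6 over the LM2 libraries. The extracellular superoxide dismutase Sod3 fell by 3.41 on the log2 scale, from 15.1 to 1.41 CPM. The splicing regulator Mbnl3 fell by 3.16, the secreted protein Wfdc1 by 2.90, the Rac regulator Chn1 by 2.74, the semaphorin Sema6d from 24.0 to 3.72 CPM and Isoc1 by 2.50. Gli1, a transcription factor and target of hedgehog signalling, fell 5.14-fold from 77.2 to 15.0 CPM. Neuregulin Nrg2 fell by 2.15, butyrylcholinesterase Bche by 2.13, the lysosomal galactosylceramidase Galc by 2.10 and the synaptic scaffold Shank2 by 2.07. All 24 genes kept their call in every other setting that was tested gene by gene.

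**Figure D1:**
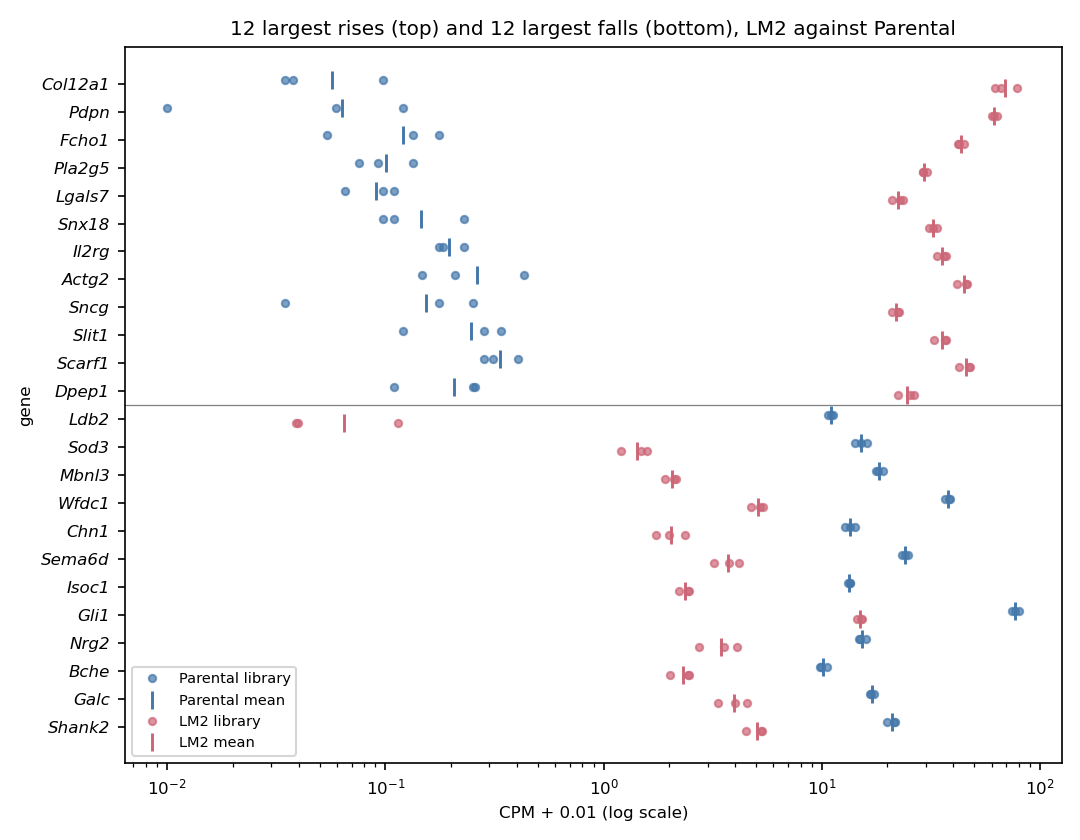
Expression of the 12 genes with the largest rises and the 12 with the largest falls among named genes of at least 10 CPM in the higher line and no overlap between the lines, as CPM plus 0.01 on a log axis, with a point for each of the 3 Parental (blue) and 3 LM2 (red) libraries and a bar for each mean. Col12a1 lies near 0.0468 CPM in Parental and 68.8 CPM in LM2, while Ldb2 is 184-fold lower in LM2.

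Abundant genes that changed included genes of the matrix. Col1a1, the main chain of collagen I, rose from 659 to 1330 ± 38.1 CPM (log2 fold change 1.01 ± 0.03, edgeR adjusted p = 5.61e-19). Col6a3, a chain of collagen VI, rose 9.80-fold from 147 ± 2.04 to 1444 ± 149 CPM. Igfbp5, which encodes a binding protein of insulin-like growth factors, rose 49.5-fold from 11.8 to 585 CPM and had the smallest adjusted p of all genes, 3.67e-30 by edgeR. The smooth muscle actin Acta2 rose by 3.58 on the log2 scale, from 39.5 to 473 CPM, and the secreted glycoprotein Fstl1 2.04-fold from 246 to 500 CPM. S100a4, a calcium-binding protein often used as a fibroblast and motility marker, fell 2.08-fold from 329 to 158 CPM, although 49.2% of its 31-base words are shared with other genes.

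Of 38 gene lists, 35 had at least 5 tested members and 19 were called by limma's camera with its preset correlation of 0.01. Each call was made with that preset value, and none held with an estimated correlation. The estimate was well above the preset for some lists, as the interferon response (0.563). For others it was at or below the preset, as Wnt pathway targets (-0.106) and YAP and TAZ targets (0.004). Loss of those calls does not show that their members vary together. The adjusted p with an estimated correlation is given beside each list.

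The type I interferon response stood furthest from the other genes. Of 36 tested members 29 rose, 2 fell and 5 did not pass, and adjusted over the list alone 30 rose and 3 fell. The median log2 fold change of the list was 1.60. Camera gave an adjusted p = 3.24e-06, and adjusted p = 0.533 with an estimated correlation, with an inter-gene correlation of 0.563. Ifi44 rose 29.8-fold from 0.571 ± 0.0885 to 17.1 ± 3.68 CPM, and Oasl2, of the family of oligoadenylate synthetases, rose 25.4-fold from 0.926 to 23.6 ± 6.24 CPM. Rtp4, which is induced by interferon, rose 18.9-fold from 0.432 to 7.98 CPM. Samd9l, an interferon-inducible growth restraint factor, fell 1.66-fold from 40.3 to 24.2 CPM. The list medians relative to the Parental mean were 1.203, 1.48 and 1.83 in LM2 replicates 1 to 3 and between -0.06 and 0.09 in the Parental libraries. Leukocyte genes, which such a rise could accompany, were near the floor, with Ptprc at 0.0651 CPM in Parental and 0.0745 CPM in LM2.

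Antigen presentation by MHC class I moved in the same direction. Of 23 members 18 rose and 3 fell, with the same counts adjusted over the list alone, and 2 did not pass (camera adjusted p = 0.000314, and adjusted p = 0.346 with an estimated correlation). Psmb8, a subunit of the immunoproteasome, rose 6.12-fold from 7.27 ± 0.157 to 44.5 ± 3.43 CPM, and its partner Psmb9 rose 2.63-fold from 2.04 to 5.36 CPM. The heavy chain gene H2-K1 rose 2.45-fold from 28.8 to 70.5 CPM, with 22.8% of its 31-base words shared with other genes. Tapbpl, a peptide editor of class I molecules, fell 1.54-fold. H2-T23, with 0.464 CPM in Parental and 0.449 in LM2, and H2-Q4, with 1.39 and 1.61 CPM, did not pass. MHC class II genes and immune checkpoint ligands were not called as a list (13 tested, 6 higher and 2 lower, also adjusted over the list alone, camera adjusted p = 0.147, adjusted p = 0.55 with an estimated correlation). In that list Nectin2 and Pvr, both ligands of lymphocyte receptors, rose 1.68-fold and 1.33-fold. Cd276 rose 1.29-fold, and H2-DMa fell 1.72-fold.

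NF-kB targets and secreted signals were also higher. Of 23 NF-kB targets 15 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.0188, adjusted p = 0.346 with an estimated correlation). The adhesion receptor Icam1 rose from 0.904 to 5.45 CPM, the apoptosis inhibitor Birc3 3.34-fold and the receptor Cd40 2.88-fold, while the NF-kB subunit Rel fell 1.33-fold. Nfkbiz, at 12.1 CPM in Parental and 11.8 CPM in LM2, did not pass. Of 17 chemokines and cytokines 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0194, adjusted p = 0.266 with an estimated correlation). Cx3cl1 rose 2.24-fold from 7.14 to 16.0 CPM, the macrophage growth factor Il34 1.98-fold from 13.8 to 27.3 CPM, Pdgfa 1.48-fold and the monocyte chemokine Ccl2 1.47-fold from 5.27 to 7.72 CPM. Vegfd, with 1.86 and 1.96 CPM, did not pass.

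Most tested basal genes of the mammary epithelium were higher. Of 11 basal and myoepithelial genes 8 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.00421, adjusted p = 0.266 with an estimated correlation). Besides Acta2, the myosin light chain kinase gene Mylk rose 15.9-fold from 6.52 ± 0.285 to 104 ± 2.43 CPM and the basal keratin Krt14 7.67-fold from 1.11 to 8.47 CPM. Egfr, the receptor of epidermal growth factor, fell 2.00-fold from 36.1 to 18.0 CPM, and Cnn1, at 0.437 and 0.563 CPM, did not pass. Of 13 tested genes of epithelial adhesion and keratins 9 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.0312, adjusted p = 0.271 with an estimated correlation). Epcam, an epithelial adhesion molecule, rose 94.3-fold from 0.154 to 15.0 CPM, Krt8 1.35-fold from 420 to 568 CPM and the desmosomal Pkp3 1.32-fold, while Jup, plakoglobin, fell 1.37-fold from 69.2 to 50.4 CPM. The main epithelial cadherin Cdh1 was not tested because it lay at 0.187 CPM in Parental and 0.0938 CPM in LM2. The list holds 27 genes, and the others not tested also lay below the low-count filter. Among them were Krt18, at 0.0449 and 0.125 CPM, and Cldn7, at 0.220 and 0.160 CPM. Some risers stayed low in LM2, as Elf3 at 1.60 CPM and Dsp at 0.471 CPM. Luminal and hormone receptor genes were not called (8 tested, 1 higher and 4 lower, 2 and 4 adjusted over the list alone, camera adjusted p = 0.277, adjusted p = 0.55 with an estimated correlation), although Erbb3 fell 1.76-fold, Tfap2a 1.32-fold and Erbb2 1.29-fold and Xbp1 rose 1.26-fold.

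Mesenchymal and matrix genes were mostly higher. Of 21 mesenchymal genes 14 rose and 2 fell, 15 and 2 adjusted over the list alone (camera adjusted p = 0.00997, adjusted p = 0.266 with an estimated correlation). Tagln, an actin-binding protein of smooth muscle, rose 4.61-fold from 1.41 to 6.56 CPM and the crosslinking enzyme Loxl2 1.74-fold from 105 to 182 CPM, while S100a4 was among the falls. Pdgfrb at 49.1 and 47.9 CPM and Twist2 at 41.8 and 43.3 CPM did not pass. Of 28 collagens and matrix glycoproteins 17 rose and 10 fell, 18 and 10 adjusted over the list alone (camera adjusted p = 0.0391, adjusted p = 0.55 with an estimated correlation). Thbs2, a matricellular protein, rose 5.34-fold from 1.14 to 6.11 CPM, and Col3a1 1.51-fold from 167 to 253 CPM. Col6a1 fell 1.52-fold from 1316 ± 14.4 to 867 ± 29.6 CPM while Col6a3, which joins it in collagen VI, rose. Col1a2, which pairs with Col1a1 in collagen I, was at 0.926 CPM in Parental and 0.232 CPM in LM2. Of 24 matrix proteases and inhibitors 13 rose and 3 fell, 14 and 3 adjusted over the list alone (camera adjusted p = 0.0153, adjusted p = 0.266 with an estimated correlation). Plat, the tissue plasminogen activator, rose 2.77-fold from 7.85 to 21.8 CPM and the gelatinase Mmp2 2.49-fold from 13.6 to 33.9 CPM. Lysosomal Ctsd fell 1.22-fold, and Ctsb at 381 and 388 CPM did not pass.

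Of 14 integrins 10 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.022, adjusted p = 0.346 with an estimated correlation). Itgb2, best known from leukocytes, rose 13.5-fold from 0.921 to 12.5 CPM, Itgb7 4.71-fold from 9.16 to 43.0 CPM and the laminin receptor chain Itga7 2.40-fold, while the collagen receptor chain Itga1 fell 2.36-fold from 22.5 to 9.54 CPM. Genes named in earlier work on lung metastasis of breast cancer were not called (14 tested, 6 higher and 5 lower, also adjusted over the list alone, camera adjusted p = 0.866, adjusted p = 0.917 with an estimated correlation). Nedd9, a scaffold of focal adhesions, rose 2.82-fold and Mmp2 rose, while Man1a fell 1.78-fold and the growth factor Ereg 1.53-fold. The median of the list was 0.03 and its mean -0.01. Id3, at 100.4 CPM in Parental and 100.3 CPM in LM2, did not pass.

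Targets of several signalling pathways were tested as lists. Of 20 YAP and TAZ targets 16 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.000736, adjusted p = 0.266 with an estimated correlation). The matricellular genes Ccn2 and Ccn1 rose 3.18-fold from 10.9 to 34.6 CPM and 2.44-fold from 29.4 to 71.6 CPM, and the tumour suppressor Dlc1 rose 2.31-fold. Tead4, a DNA-binding partner of YAP, fell 1.55-fold. Of 21 TGF-beta targets 14 rose and 4 fell, also adjusted over the list alone (camera adjusted p = 0.00737, adjusted p = 0.437 with an estimated correlation). The latent TGF-beta binding protein Ltbp2 rose 16.3-fold from 0.582 to 9.65 CPM and the ligand Tgfb2 5.81-fold from 4.71 to 27.4 CPM, while Ldlrad4, an inhibitor of the pathway that shares 50.3% of its 31-base words with other genes, fell 1.61-fold. Of 10 Wnt pathway targets 5 rose and none fell, also adjusted over the list alone (camera adjusted p = 0.0223, adjusted p = 0.266 with an estimated correlation). The transcription factor Tcf7 rose 6.29-fold from 10.7 to 67.5 CPM and the cyclin Ccnd1 1.09-fold, while Axin2, the usual readout of the pathway, was at 11.7 and 12.1 CPM and did not pass. The Wnt call was lost without Parental replicate 1 (camera adjusted p = 0.0813), LM2 replicate 1 (0.0676) or LM2 replicate 3 (0.0832), without a low-count filter (0.168) and with at least 1 CPM in 3 libraries (0.112). The Notch pathway was not called (11 tested, 5 higher and 2 lower, 5 and 3 adjusted over the list alone, camera adjusted p = 0.752, adjusted p = 0.813 with an estimated correlation), with Notch1 and its target Nrarp falling 1.52-fold and 2.56-fold and Notch2 and Lfng rising 1.48-fold and 1.62-fold.

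Growth factor signalling genes went both ways. Of 20 genes of MAP kinase feedback 13 rose and 4 fell, also adjusted over the list alone, and the list was not called (camera adjusted p = 0.135, adjusted p = 0.346 with an estimated correlation). The phosphatase Dusp1 rose 2.45-fold, while Etv1 fell 1.78-fold, Etv4 1.68-fold from 132 to 78.7 CPM and the ERK phosphatase Dusp6 1.55-fold. Receptor tyrosine kinases and ligands were not called either (23 tested, 11 higher and 7 lower, also adjusted over the list alone, camera adjusted p = 0.374, adjusted p = 0.738 with an estimated correlation). Mertk rose 2.01-fold from 2.75 to 5.54 CPM, while Met, the receptor of hepatocyte growth factor, fell 1.59-fold from 118 to 74.8 CPM.

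**Figure D2:**
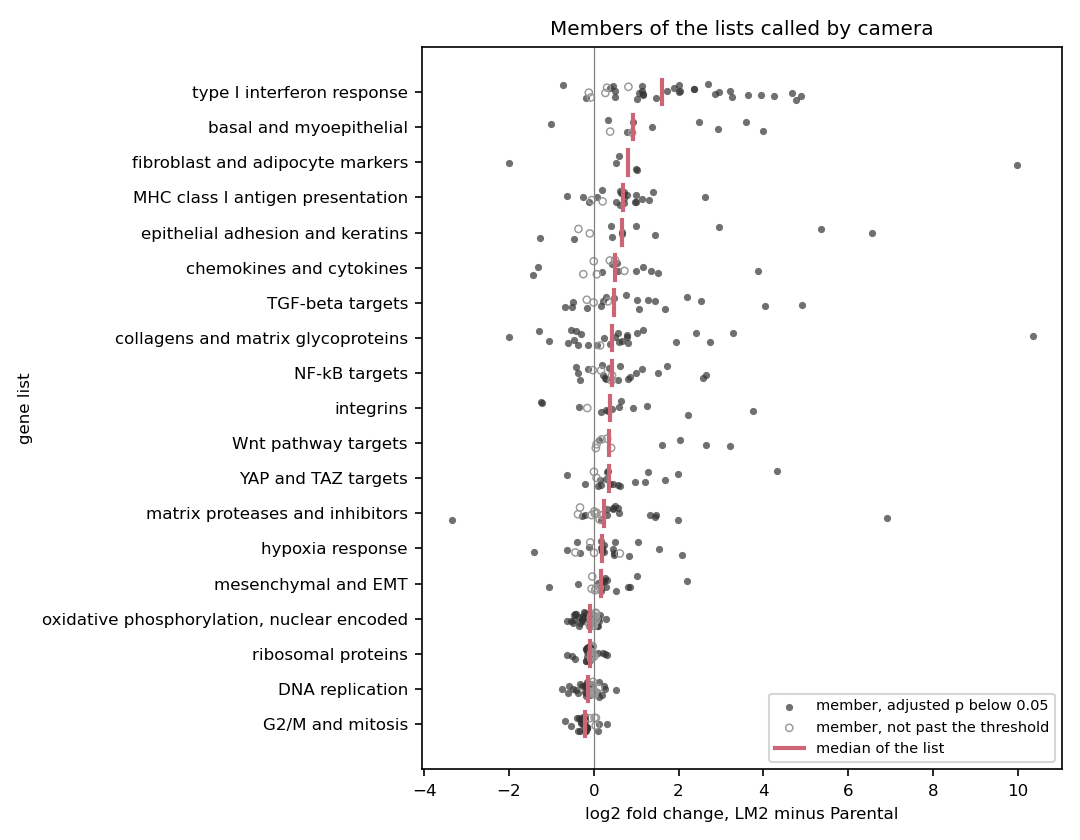
Log2 fold change of LM2 minus Parental for each tested member of the 19 lists called by camera, 1 row per list, with filled points past the threshold, open points not past it and a red bar at the list median. The interferon list has the highest median, 1.60, with members up to 4.90, while the medians of the 4 lists called lower lie between -0.21 and -0.09.

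Mitotic genes were lower by small amounts. Of 30 genes of G2/M and mitosis 23 fell and 3 rose, also adjusted over the list alone, with a median of -0.21 (camera adjusted p = 0.000422, adjusted p = 0.266 with an estimated correlation). Ckap2 fell 1.61-fold, the mitotic kinase Cdk1 1.45-fold from 204 to 140 CPM and Kif23 1.32-fold, while Cdc20 rose 1.24-fold from 213 to 263 CPM. Cdk1 lies on chromosome 10 and Ckap2 on chromosome 8, where most genes were lower, and Cdc20 on chromosome 4, where most were higher. When each gene was centred on the median of its chromosome, a setting chosen after seeing the data, 26 members were lower and 2 higher (camera adjusted p = 4.48e-07), so the shifts of chromosomes did not account for the call. Of 38 DNA replication genes 22 fell and 7 rose, 8 rising adjusted over the list alone (camera adjusted p = 0.0223, adjusted p = 0.55 with an estimated correlation). Prim1, a primase subunit, fell 1.69-fold, Mcm5 1.53-fold and Rrm2 1.49-fold from 244 to 163 CPM, while the transcription factor E2f1 rose 1.44-fold, and Mcm7 and Pcna did not pass. After the same centring the replication list lost its call (camera adjusted p = 0.0541), with 21 members lower, 10 higher and a median of -0.11 against -0.13 before, so most of the change stayed. Targets of p53 and CDK inhibitors were not called (23 tested, 10 higher and 8 lower, also adjusted over the list alone, camera adjusted p = 0.44, adjusted p = 0.55 with an estimated correlation). Trp53inp1 rose 11.9-fold from 0.935 to 11.1 CPM, Sesn2 1.67-fold and Plk2 1.63-fold, Gtse1 fell 1.24-fold, and Cdkn1a, the p53 target p21, was at 34.6 and 36.7 CPM and did not pass.

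Of 51 ribosomal protein genes 35 fell and 4 rose, 36 and 4 adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.00103, adjusted p = 0.55 with an estimated correlation). Rps12, Rps15 and Rpl32 fell 1.54-fold, 1.42-fold and 1.36-fold. Rps12 and Rps15 lie on chromosome 10, but after centring on chromosomes 38 members were lower and 1 higher (camera adjusted p = 1.99e-05). Rps15 and Rpl32 share 49.8% and 32.6% of their 31-base words with other genes, and levels are likewise less certain for Loxl2 (46.4%), Ctsd (33.2%), Krt8 (32.3%), Ly6a (31.9%), Mcm7 (30.9%), Me1 (30%), Gstm1 (28.8%), Krt14 (28.2%) and Cdc20 (26.7%). Ribosomal protein genes took 6.45% to 6.52% of the counts in Parental and 5.88% to 6.08% in LM2.

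Of 50 nuclear genes of oxidative phosphorylation 28 fell and 7 rose, also adjusted over the list alone, with a median of -0.09 (camera adjusted p = 0.00859, adjusted p = 0.346 with an estimated correlation). The complex I genes Ndufa5 and Ndufa9 fell 1.54-fold and 1.45-fold, Ndufs7 fell by 0.48 on the log2 scale, and Sdhb of complex II rose 1.22-fold. After centring on chromosomes the list kept its call, with 24 members lower and 5 higher (camera adjusted p = 0.00973). The change of Sdhb, on chromosome 4, turned to -0.09 in that setting, and that of Ndufs7, on chromosome 10, no longer passed (edgeR adjusted p = 0.0509). Genes encoded by the mitochondrial DNA were not called (13 tested, 2 higher, none adjusted over the list alone, camera adjusted p = 0.131, adjusted p = 0.738 with an estimated correlation), but were called without Parental replicate 3 (camera adjusted p = 0.0168). The members past the threshold, mt-Co1 and mt-Nd4, lost their calls without LM2 replicate 3 (edgeR adjusted p = 0.0929 and 0.14) and in several other settings, and over 60% of their 31-base words are shared with other genes.

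Genes of the response to low oxygen were marginally higher. Of 24 hypoxia response genes 15 rose and 5 fell, also adjusted over the list alone (camera adjusted p = 0.0495, adjusted p = 0.55 with an estimated correlation). Ndrg1 rose 2.91-fold from 32.3 to 94.0 CPM, Bnip3, of mitophagy, 2.07-fold and the glucose transporter Slc2a1 1.79-fold from 101 to 181 CPM, while the carbonic anhydrase Car12 fell 1.54-fold. The call was lost without Parental replicate 2 (camera adjusted p = 0.0512), Parental replicate 3 (0.0842) or LM2 replicate 3 (0.0582), under 2 other scalings (0.0512 and 0.0542) and in protein-coding genes alone (0.0565). It was kept without a low-count filter (0.0278) and after centring on chromosomes (camera adjusted p = 0.004), where 16 members were higher and 2 lower.

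The lists of glycolysis and of lipid metabolism were not called. Glycolysis had 13 higher and 9 lower of 25 genes, also adjusted over the list alone (camera adjusted p = 0.44, adjusted p = 0.683 with an estimated correlation). Eno3 rose 1.55-fold, Pfkl and the transporter Slc2a3 fell 1.48-fold and 1.68-fold, and lactate dehydrogenase Ldha was at 1460 CPM in both lines. Cholesterol synthesis had 5 higher and 10 lower of 24, also adjusted over the list alone (camera adjusted p = 0.44, adjusted p = 0.862 with an estimated correlation), with Dhcr7 rising 1.47-fold and Lss and Cyp51 falling 1.58-fold and 1.36-fold. Fatty acid synthesis and storage had 7 higher and 9 lower of 22, 8 and 9 adjusted over the list alone (camera adjusted p = 0.908, adjusted p = 0.932 with an estimated correlation). In that list the median was -0.04, the mean 0.18 and the direction by camera down. Acacb, of malonyl-CoA synthesis at mitochondria, rose 17.9-fold and raised the mean. Plin2, which coats lipid droplets, rose 1.63-fold and the malic enzyme Me1 1.55-fold, and Acsl4 fell 1.36-fold. Fatty acid oxidation had 10 higher and 8 lower of 24, also adjusted over the list alone (camera adjusted p = 0.708, adjusted p = 0.85 with an estimated correlation), with Decr1 rising 2.34-fold and Acaa2 and Echs1 falling 1.63-fold and 1.36-fold.

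Stress lists also went both ways. NRF2 targets and glutathione genes had 10 higher and 12 lower of 29, also adjusted over the list alone (camera adjusted p = 0.991, adjusted p = 0.996 with an estimated correlation). Heme oxygenase Hmox1 fell 2.42-fold from 199 ± 6.67 to 82.2 ± 5.45 CPM, while Aldh3a1 rose 3.24-fold, Gstm1 1.57-fold and Gstp2 8.06-fold, the last with 60.3% of its 31-base words shared with other genes. The median of the NRF2 list was -0.01 and its mean 0.13. The list of serine synthesis, amino acid stress and the unfolded protein response had 15 higher and 9 lower of 31, also adjusted over the list alone (camera adjusted p = 0.36, adjusted p = 0.683 with an estimated correlation), and was called after centring on chromosomes (camera adjusted p = 0.0106). Atf3 rose 3.26-fold and Sdf2l1 2.23-fold, while Shmt2, of mitochondrial serine metabolism and on chromosome 10, fell 1.51-fold from 759 to 504 CPM. Stemness and drug transport genes were not called (15 tested, 7 higher and 4 lower, also adjusted over the list alone, camera adjusted p = 0.502, adjusted p = 0.683 with an estimated correlation), with the transporters Abcg2 and Abcb1b falling 2.83-fold and 1.81-fold and Aldh1a3 and Ly6a rising 1.49-fold and 1.34-fold. The median of that list was 0.14 and its mean -0.22.

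Markers of other cell types differed from list to list. Fibroblast and adipocyte markers were called (6 tested, 5 higher and 1 lower, also adjusted over the list alone, camera adjusted p = 0.0223, adjusted p = 0.313 with an estimated correlation), and the call was lost without a low-count filter (camera adjusted p = 0.429). Its risers were Pdpn, Col1a1, Col3a1, Pdgfra, which rose 1.44-fold, and Dpt, while Col1a2 fell, and Dcn stayed at 0.0816 CPM in Parental and 0.0781 CPM in LM2. Endothelial markers were not called (7 tested, 2 higher and 2 lower, also adjusted over the list alone, camera adjusted p = 0.866, adjusted p = 0.917 with an estimated correlation), with Eng rising 1.14-fold from 144 to 163 CPM and Egfl7 falling 2.04-fold, a median of 0.03 and a mean of -0.04. Leukocyte markers had only 3 tested members, of which Lyz2 fell from 2.51 to 0.831 CPM, Itgax fell from 0.353 to 0.0289 CPM and Cd68 rose 1.53-fold to 2.68 CPM, with the same counts adjusted over the list alone. Lung epithelium markers had 4 tested members, of which Hopx rose 2.17-fold from 10.2 to 22.1 CPM and Ager rose from 0.947 to 3.45 CPM, also adjusted over the list alone, while the surfactant genes Sftpb at 0.147 and 0.131 CPM and Sftpc at 0 in both lines were not tested. Of the sex-linked genes Kdm5d and Uty were tested, and neither passed, also adjusted over the list alone (1.36 and 1.55 CPM, and 0.264 and 0.402 CPM). Dpt, Itgax, Ager, Cdh1, Krt18, Cldn7, Elf3, Dsp, Ptprc, Lyz2, Col1a2, Dcn and the surfactant genes lay outside the rule for named genes and were chosen after their values were seen.

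Expression differed by chromosome. Over 8724 protein-coding genes of at least 10 CPM, the median log2 fold change was 0.38 on chromosome 4, -0.38 on chromosome 10 and -0.33 on chromosome 8, and -0.21 and -0.20 on chromosomes 6 and 12. On the other chromosomes it lay between -0.10 and 0.05. In 10000 shuffles of genes over chromosomes the largest absolute median was 0.10. On chromosome 4, 94.3% of 557 genes were higher in LM2, on chromosome 10, 89% of 437 were lower, and on chromosome 8, 84% of 501 were lower. All 38 windows of 40 neighbouring genes on these 3 chromosomes lay on the side of their chromosome. The medians of the single LM2 libraries on chromosome 4 were 0.38, 0.37 and 0.37. Chromosomes were examined after other results had been seen.

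**Figure D3:**
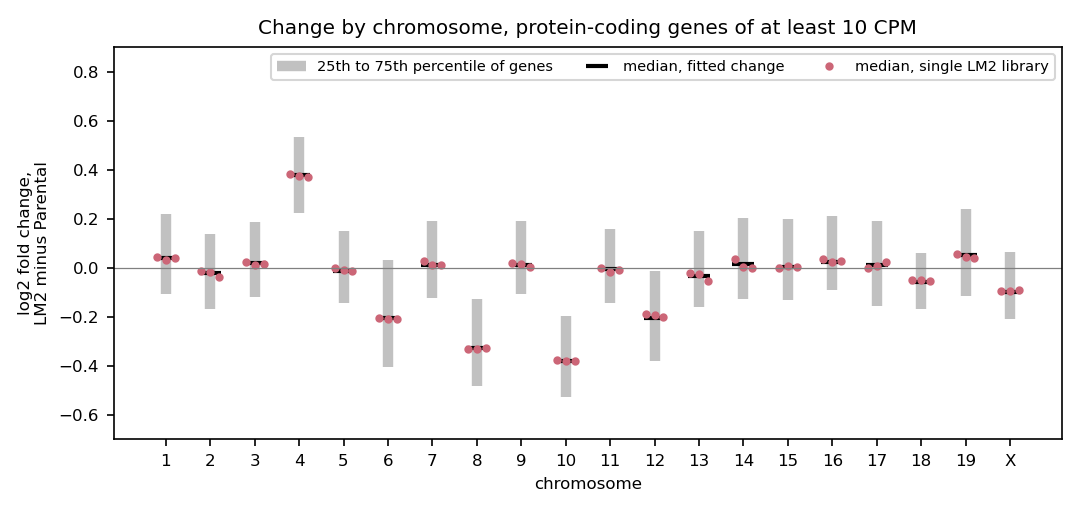
Log2 fold change of LM2 minus Parental by chromosome for protein-coding genes of at least 10 CPM, with grey bars from the 25th to the 75th percentile of genes, black bars at the median and red points for the median of each LM2 library. Chromosome 4 lies at 0.38 and chromosomes 8 and 10 lie at -0.33 and -0.38, with all 3 LM2 libraries at the same level.

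The authors' deposited table gives a fold change for 11005 gene symbols, of which 10927 could be set beside the values here. Across these genes, which are not independent replicates, Pearson's r between the deposited and the own log2 fold changes was 0.957 and Spearman's coefficient 0.958, with a median absolute difference of 0.024. Among 7607 genes that passed here and were in the authors' deposited table, 7501 (98.6%) had the same sign. Of the 1140 genes called here with an absolute log2 fold change over 1, 724 were in that table. Of 791 compared genes with a deposited value over 1 in size, 659 were also called here over 1 with the same sign. In 91 genes the values differed by more than 1. In the authors' deposited table Col12a1 stands at 8.92, Pdpn at 9.10, Col1a1 at 0.79, Gli1 at -2.35 and Ldb2 at -6.16. Both sets of values come from the same libraries, so their closeness concerns the processing alone.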

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

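The tests in this part were chosen only after the results were seen, apart from the test on genes of 1 to 10 CPM, whose prediction was written before it was run. Among 1078 transcripts with no gene in the annotation used here, which were left out of the tests of genes, 269 were tested by edgeR and 83 differed between LM2 and Parental, 47 higher and 36 lower. At an unadjusted p below 0.05 the count was 96. An absolute log2 fold change over 1 was reached by 31 of the 83. Their genes were not identified here.

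The first pattern weighed is the shift of whole chromosomes. After the trend on GC content and transcript length was removed, the median of chromosome 4 was 0.390 against 0.377 before. On chromosomes 8 and 10 it was -0.324 and -0.383, against -0.329 and -0.381 before. These values argue against base composition. Without that removal, 94.3% of the genes of chromosome 4 lay on the side of its median, as did 14 of 14 windows. That argues against a few strong genes or a single segment on chromosome 4. Genes of 1 to 10 CPM, which had not been used to find the shift, had a median of 0.466 on chromosome 4 (95% bootstrap interval 0.379 to 0.744) and -0.232 on chromosome 10 (-0.306 to -0.166), while on chromosome 8 the median was -0.194 and its interval, -0.340 to 0.010, includes 0. These 3 medians met the prediction and were the highest and the 2 lowest of all chromosomes. Without a shift among abundant genes, chromosomes 1, 2, 5, 7, 9, 15 and 19 also had medians and intervals above 0. The largest of these medians were 0.221, 0.225 and 0.255, on chromosomes 1, 9 and 15. An interval above 0 is thus not particular to chromosome 4. The intervals come from resampling genes, which are not independent replicates. A difference in the number of copies of these chromosomes between the lines is a candidate explanation, but DNA was not measured, and a change in regulation along them stays open.

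The second pattern is the higher interferon response in LM2. Leukocytes in the LM2 cultures would bring their abundant transcripts, but the highest LM2 mean of Ptprc, Tyrobp, Fcer1g, Laptm5 and Cd52 was 0.0745 CPM. Of the 3 leukocyte markers tested, Cd68 rose to 2.68 CPM in LM2, while Lyz2 and Itgax fell. Outside the marker list, Itgb2, best known from leukocytes, rose to 12.5 CPM in LM2 and the interleukin receptor gene Il2rg to 35.7 CPM. A single library that stands apart is also argued against, because the lowest LM2 library still had a list median of 1.203 on the log2 scale. Culture handling that differed between the lines, and the difference between the lines itself, were not tested and stay open.

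The third pattern is the set of 27 genes under 0.5 CPM in each Parental library and over 5 CPM in each LM2 library, on 17 chromosomes, against 1 gene (Ldb2) the other way. Fibroblasts in the LM2 cultures are argued against, since the highest LM2 mean of Col1a2, Dcn, Lum, Fap and Postn was 0.232 CPM beside 61.7 CPM for Pdpn. Other fibroblast markers, Col1a1, Col3a1 and Pdgfra, rose, but they were already at 659, 167 and 126 CPM in Parental. Reads shared with other genes are argued against for the set as a whole, with a median of 0.31% of 31-base words shared, although 3 of the 27 genes (Gmpr, Il2rg and Nlrp4c) share over 10% and up to 28.7%. A difference between the lines, such as the growth of LM2 from few cells, was not tested and stays open.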

How the results depend on the processing

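Centring on chromosome medians was chosen after seeing the data, and the other alternatives before. The number of genes that differ stayed within 1.5 times of 8272 in the settings that test gene counts, not transcripts, against no change. It ranged from 6985 (effective length offset) to 8596 (no low-count filter), with 7469 by DESeq2 and 8302 by limma voom. With transcripts as features 6869 transcripts of 5480 genes were called, fewer genes by over 1.5 times, and the cause was not tested. Tested against a log2 fold change of 1, 628 genes were called, by construction fewer. The 1140 genes with an absolute log2 fold change over 1 became 754 with at least 1 CPM in 3 libraries, which tests fewer genes. The share of calls that were higher, 50.2%, became 47.4% without a low-count filter and 54.1% after centring on chromosomes. The share of calls with the sign of the authors' deposited table, 98.6%, became 99.0% by DESeq2, 99.3% with the effective length offset and 92.2% after centring. Centring takes chromosome medians off the values here and leaves the deposited ones as they stood, so some signs turn by construction. In the other settings the cause was not tested for the share higher or for the agreement.

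Of the 19 lists called by camera, 0 were called with an estimated inter-gene correlation, while fry, which does not compare a list with other genes, called 30. Fatty acid synthesis reversed in direction under fry (adjusted p = 0.0088). Whether the replicate numbers pair the libraries is not stated in the labels. The correlations of same-numbered deviations were -0.078, 0.045 and 0.015, and those of differently numbered ones lay between -0.09 and 0.073. These values show no sign of pairing but cannot exclude it. With the replicate number as a block 8250 genes were called, 1135 of them with an absolute log2 fold change over 1, and 18 lists, with collagens (adjusted p = 0.0643) and hypoxia (0.0721) lost and mitochondrially encoded genes gained (0.0257). The gap between the lowest within-line and the highest between-line correlation was 0.0273, and 0.0176 by Spearman and 0.0083 without a low-count filter.

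Leaving out 1 library at a time gave 7778 to 8258 genes, 1157 to 1225 with an absolute log2 fold change over 1, 49.2% to 50.6% higher, 98.4% to 98.8% with the sign of the authors' deposited table and 17 to 19 lists.

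After centring on chromosomes the log2 fold changes of 8 named genes that were called before or after it turned sign, by construction. Among them were Cdc20 (to -0.072), Kif2c (-0.331), Cdkn2c (-0.369), Pgk1 (0.056), G6pdx (0.084) and Sdhb (-0.09). Turns of sign in genes called neither before nor after were not counted. Of 153 named genes past the threshold, 4 lost their call in any setting (mt-Co1, mt-Nd4, Cpt2 and Ndufs7), the last 2 only after centring. The median log2 fold change of all tested genes was -0.0037 under TMM, 0 with library totals and 1e-04 with median-of-ratios scaling. Genes near the low-count filter are limited by depth, as Col12a1 and Pdpn in Parental.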

Other observations

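The tests in this part were chosen only after the results were seen, on 3 gene lists written after the largest changes were known and on 146 groups of genes that share a symbol stem. Contractile and smooth muscle genes were mostly higher in LM2, with 23 of 26 tested genes higher and 2 lower by edgeR. Beside Acta2 and Actg2, the skeletal muscle actin Acta1 went from 0.556 ± 0.210 to 47.0 ± 2.94 CPM (SD, n = 3 each), the regulatory light chain Myl9 from 4.50 to 28.6 CPM, the muscle creatine kinase Ckm from 0.0661 to 7.05 CPM and sarcospan, Sspn, from 0.0889 to 10.2 CPM. Widely expressed members moved less, as Tpm1, Vcl and Srf rose 1.56-fold, 1.57-fold and 1.48-fold, and Csrp2 and Myl6 fell 2.26-fold and 1.11-fold.

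Hedgehog pathway genes other than Gli1 went both ways. The receptor gene Ptch1 fell from 152 to 94.6 CPM and the transducer Smo from 259 to 183 CPM. Gli2 rose from 0.359 to 5.21 CPM and the coreceptors Boc and Cdon from 0.109 to 1.96 CPM and from 3.56 to 27.0 CPM. Axon guidance genes had 15 of 28 higher and 7 lower and were not called by camera (adjusted p = 0.156 over the 3 lists, and adjusted p = 0.679 with an estimated correlation), with Slit1 and Ncam1 the largest rises and Sema6d the largest fall.

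One hypothesis was that contractile genes rise as a group in LM2. The whole list gave a camera adjusted p = 3.06e-09 and adjusted p = 0.0125 with an estimated correlation, but 10 of its members had prompted the list. Over the 16 others, 14 rose and 2 fell with a median of 0.57, and camera gave an adjusted p = 7.74e-05 and adjusted p = 0.0521 with an estimated correlation. The estimated correlation of these members was 0.022, close to the preset of 0.01, so it does not show strong correlated variation between them. As the results of camera fell on both sides of 0.05, whether the group moves beyond the genes first seen stays undecided in 6 libraries.

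A second hypothesis, that hedgehog genes fall as a group with Gli1, was not borne out for the list as a whole. The list mixes targets, receptors and other components of the pathway, so it does not tell whether hedgehog signalling fell. The median log2 fold change of the 13 tested genes was 0.13, with 8 higher and 5 lower and a camera adjusted p = 0.67.

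Of 146 symbol stems with at least 10 tested genes, in 292 Fisher's exact tests, 1 passed after adjustment. Zinc finger genes named Zfp were more than 2-fold higher in 6 of 342 cases (1.75%), against 6.5% of all tested genes (adjusted p = 0.0149), so they were less often among the large rises. The stem Ifi had 5 of 11 (adjusted p = 0.0556).

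The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 8272 genes, 1140 with an absolute log2 fold change over 1, and 19 lists, and only 1 of the 10 splits reached each of these. The highest of the other splits gave 0 genes by edgeR, 0 with an absolute log2 fold change over 1, and 11 lists. Each other split puts libraries of both lines in each group, so the difference between the lines widens the spread within groups. A count of genes near 0 is thus largely built into these splits. Part of the difference between the lines also stays in their contrast, so these counts do not show what chance gives.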
